A study of Mus musculus with 12 samples.

How the data were processed

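RNA from mouse dorsal root ganglion (DRG) material was sequenced in 12 libraries, in 4 groups of 3. The mice carried an HA-tagged copy of the ribosomal protein gene Rpl22 that Advillin-Cre switches on in sensory neurons (the RiboTag method), so that ribosomes of these neurons can be pulled down with an antibody against HA. The input groups hold total RNA and the IP groups hold RNA from the anti-HA pull-down. In each fraction 1 group had received AAV-shGpr151, a virus carrying a short hairpin RNA against Gpr151, and the other AAV-shGpr151 together with AAV-e5'UTR. The labels do not say what the e5'UTR insert is or from which gene it comes, and no group with a non-targeting hairpin was analysed here. The design text speaks of cultured neurons taken after a preconditioning sciatic nerve injury, whereas the protocol in the labels speaks of DRGs collected fresh, and the sources used here do not settle which of these was sequenced.

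The values are the authors' deposited estimated counts per gene, written as whole numbers, in a table of 14675 Ensembl gene IDs and 12 columns, each matched to 1 sample by its name. Per the labels' protocols, the libraries were made with an Oxford Nanopore cDNA-PCR barcoding kit. The submitters' processing notes name minimap2, Salmon and the mouse builds GRCm39 and mm39, without versions or roles. The counting settings, the annotation release, any filter and the treatment of reads that match more than 1 gene are not given in the sources used here. The lowest total of a gene over the 12 columns was 13 counts. A symbol was found for 13191 gene IDs (89.9%), and the 1484 IDs without one held 11.0% of the counts. The reference with gene coordinates available here is of another build, GRCm38, so no coordinates are given, and it was used only for which genes neighbour each other.

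Before any test the 3 columns of each group were compared with a chi-square test per gene, over genes with at least 30 counts in the columns compared. Because they differed by little more than counting noise and had almost equal totals, the 3 columns of a group were counted as 1 sample, called a pool. Levels are pooled counts, or CPM of the scaled library size, with exact Poisson 95% intervals. Ratios of pooled counts have exact binomial (Clopper-Pearson) 95% intervals. A fold against a pool with 0 counts was computed against a floor of 3 counts per pool. Reads from PCR-amplified cDNA cannot be taken as independent molecules, and no use of molecular identifiers was found in the sources used here. Intervals and floors therefore cover counting error only.

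The test fixed before the data were examined was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling, in 1 model of the 4 group means over all 12 columns, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The filterByExpr function (minimum count 10, minimum total 15) left 8085 genes. The biological coefficient of variation was 2.58% and TMM factors ran from 0.725 to 1.379. Since the columns of a group carry little more than counting noise, this test is a test on the reads of the pools: it compares these libraries, not the conditions, and none of the e5'UTR differences has a replicate check. All p-values measure only the spread between these columns. IP against input is the mean of both IP groups minus the mean of both input groups, and the last comparison is the interaction of fraction and e5'UTR, in the same model. Adjusted p-values in the text are from this test unless another is named.

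The 27 gene lists, also fixed before the data were examined, were injury and regeneration, pan-neuronal, nociceptor, mechanoreceptor and proprioceptor, satellite glia, Schwann cell, fibroblast, macrophage and immune, endothelial and mural, erythroid, proliferation, cytosolic ribosomal proteins (without Rpl22), translation factors, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, proteasome, integrated stress response, unfolded protein response, interferon-stimulated, immediate early, cholesterol synthesis, actin and microtubule cytoskeleton, synaptic vesicle and exocytosis, ion channels of sensory neurons, and 2 lists which, like some genes that fall under the rule below, are not reported here. Each of the 26 lists with at least 5 tested members was set against all other tested genes with limma's camera (limma 3.58.1, correlation 0.01, BH over the lists of a comparison). Camera with an estimated correlation and fry were run beside it. Each list's median was also placed among the medians of 10000 random lists of the same size matched on mean expression. The erythroid list had too few tested members for a list test. The ribosomal protein, translation factor, oxidative phosphorylation, proteasome and cytoskeleton lists were drawn by patterns of gene symbols. They thus also hold genes of like symbol, such as Eef1akmt3 among translation factors, Ndufaf7 among oxidative phosphorylation genes and Rpl7l1 among cytosolic ribosomal proteins. Their member counts are counts by symbol, and the function of each member was not checked.

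The text names, by a rule fixed with the lists, the 12 genes with the smallest p in each direction of each comparison, the fixed genes Gpr151, Rpl22, Avil, Atf3, Sprr1a, Gap43, Jun and Sox11, and up to 4 tested members of each list with the smallest p. Genes known only by number were counted and left unnamed where others were present. Any other gene is said to have been chosen after its values were seen.

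The procedure was tested on simulated counts with the library sizes of the data, pooled means and 50 genes changed at each fold. For IP against input all 4 groups were given a shared mean per gene, so the large difference between the fractions was not simulated. The spread between columns was drawn at the common 2.58% for every gene, so genes with a larger spread were not covered. For the e5'UTR effect in IP (7801 genes run) 12% of genes changed 1.25-fold, 36% of those changed 1.5-fold, 78% of those changed 2-fold and 92% of those changed 4-fold were recovered, with 6 false among 115 calls. The corresponding shares were 10%, 28%, 54% and 72% for the effect in input (7823 genes, 4 false of 86 calls), 22%, 54%, 82% and 96% for IP against input (7427 genes, 3 false of 130), and 2%, 6%, 34% and 56% for the interaction (7816 genes, 3 false of 52). Camera called the 1 changed list, raised 1.25-fold, and 0 of 20 unchanged lists in the simulated e5'UTR effect in IP. Genes were drawn independently, so correlation between genes was not simulated. The lists called higher in the real IP comparison had smaller medians (log2 0.08 to 0.26), at which camera was not tried.

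The alternatives fixed in advance were RLE (DESeq2-style) size factors, scaling by library total, DESeq2 1.42.0, limma-voom, no filter, a mean count of at least 10, an adjusted p of 0.10, the replicate number as a block (treatment and number together where input and IP are compared), only the 6 libraries compared, and leaving out each library in turn. Alternatives for normalized values did not apply to counts. A test of changes beyond 1.5-fold, a fit of the 4 pools as samples, and a fit without genes low in IP were added after seeing the data. Deposited columns not used numbered 0.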

Results

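Ribosome-bound RNA of sensory neurons and total RNA were measured in adult mouse DRG material, in which the HA-tagged ribosomal protein RPL22 marks the ribosomes of Advillin-Cre neurons. Total RNA also holds RNA of other cells. The 4 groups were input and IP RNA after AAV-shGpr151 and input and IP RNA after AAV-shGpr151 with AAV-e5'UTR (e5UTR from here on), with 3 deposited columns each. The columns held 984118 to 985277 estimated counts in input shGpr151, 975403 to 977366 in input with e5UTR, 1381220 to 1382261 in IP shGpr151 and 1514948 to 1517685 in IP with e5UTR. The 10 most abundant genes held between 8.6% and 9.4% of the counts of a pool. A count of 0 in a pool allows up to 1.42 CPM in the input pools, 0.537 CPM in IP shGpr151 and 0.495 CPM in IP with e5UTR.

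The 3 columns of a group were close to parts of a single pool of reads. Their totals differed by 0.118%, 0.201%, 0.075% and 0.18% of the mean in the 4 groups in the order above, with a variance of 0.38, 1.0, 0.2 and 1.25 times the mean, where counting alone gives about 1. The median gene's chi-square between the columns was 1.12, 1.08, 1.09 and 1.12 times the value from counting. A minority of genes exceeded it: 7.7%, 7.7%, 7.3% and 7.2% of genes had p under 0.05, where a simulated division of 1 pool gave 4.6% to 5.5%. Over all genes this excess was beyond counting noise (p = 1.1e-125, 3.9e-110, 8.6e-85 and 1.4e-89, chi-square test). Each group was therefore counted as 1 sample, a pool of its 3 columns. The e5UTR differences and the interaction have no replicate check, and their tests compare these pools, not the conditions. IP against input has 2 pools per fraction, which differ in treatment and so are not replicates of 1 condition. A fit of the 4 pools is given with it.

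**Figure D1:**
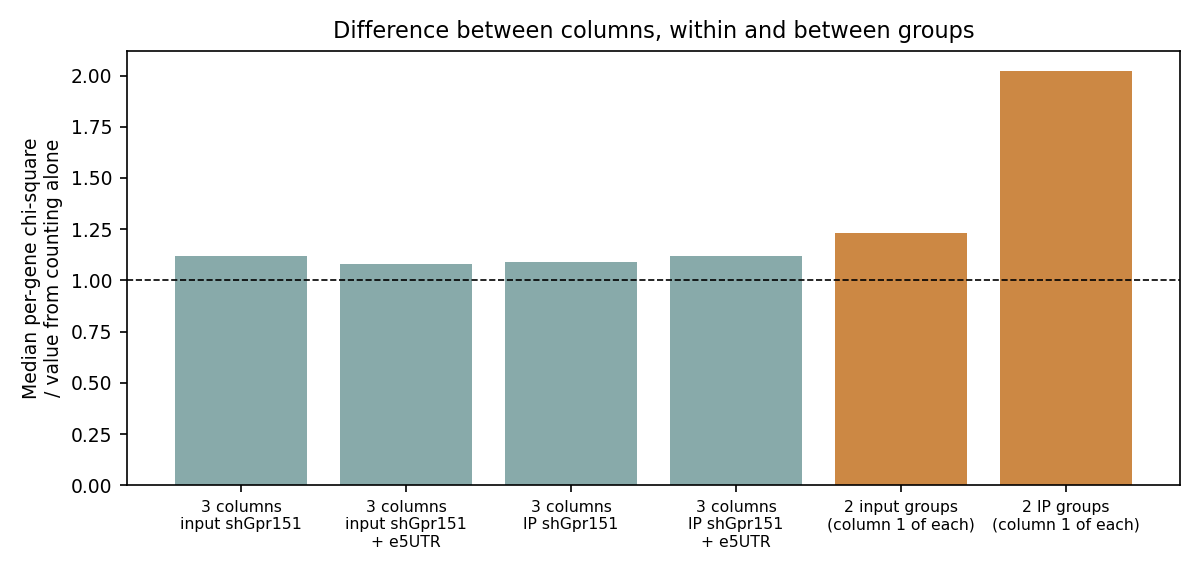
Median chi-square per gene divided by the value that counting alone gives (dashed line at 1), for the 3 columns of each group and for column 1 of the input groups and of the IP groups. The ratios were 1.08 to 1.12 within groups, 1.23 between the input groups and 2.02 between the IP groups.

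Gpr151, the target of the hairpin, encodes an orphan G protein-coupled receptor and is known to rise in sensory neurons after nerve injury. It was present in all 12 columns, with 7, 16 and 12 counts in input shGpr151, 8, 9 and 12 in input with e5UTR, 37, 37 and 34 in IP shGpr151, and 34, 44 and 50 in IP with e5UTR. The pools stood at 16.5 CPM (95% interval 11.5 to 22.9), 13.7 (9.18 to 19.7), 19.3 (15.9 to 23.3) and 21.1 (17.6 to 25.1). The ratio of e5UTR to shGpr151 was 0.832 (0.491 to 1.4) in input and 1.09 (0.84 to 1.43) in IP, and neither passed the test (adjusted p = 0.987 and 0.774), so no difference was detectable at this depth. IP against input was at log2 0.43 ± 0.20 (adjusted p = 0.051), a value that passed under some settings. These ran from 0.43 with a mean count of at least 10 (adjusted p = 0.049) to 1.32 when scaled by library total (6.2e-09), and it also passed without 7 of the 12 columns, left out 1 at a time (0.49 to 0.57). Both treatments carry the same hairpin, and a group without it was not analysed here.

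The comparison of IP with input asked which RNAs were carried by the tagged ribosomes of sensory neurons. Neuronal, regeneration, secretory and stress-response mRNAs were high in IP, whereas mitochondrially encoded RNAs, Schwann cell mRNAs and hemoglobin mRNAs were low. Of the 8085 genes tested, 3133 were higher and 3063 lower in IP (76.6% called), and 4182 of these differed by at least 2-fold. Scaled by library total instead, all log2 ratios moved up by 0.90 at the median and the split became 5216 higher and 1977 lower, so small ratios have no fixed sign. With the 4 pools as the samples, a fit added after seeing the data, 2727 genes were higher and 2924 lower. The biological coefficient of variation was 10.31% in that fit, against 2.58% over the columns. That fit did not pair an IP pool with its input, and it took the difference between the treatments as part of the spread between pools. Gene lists were not tested with pools as samples. The SEs and adjusted p-values below are from the columns and do not measure the spread between pools.

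Markers of the targeted neurons were enriched. Avil, the gene whose promoter drives the Cre, was 3.94-fold higher in IP (log2 1.98 ± 0.12 SE, adjusted p = 4.0e-24), at 96.3 and 93.3 CPM against 20.2 and 28.4. Of 28 tested members of the pan-neuronal list, 19 were higher and 5 lower (median log2 0.58, camera adjusted p = 0.0019). Thy1, a surface glycoprotein of neurons, was 5.38-fold higher (log2 2.43 ± 0.07), Prph, the intermediate filament peripherin, 4.07-fold (2.03 ± 0.04), Tubb3, the neuronal beta-tubulin, 3.66-fold (1.87 ± 0.03) and Stmn2, a regulator of axonal microtubules, 2.34-fold (1.23 ± 0.02). The synaptic vesicle and exocytosis list had 24 of 35 members higher and 2 lower (median 1.11, camera adjusted p = 0.00018), led by the granin-like Pcsk1n (7.08-fold) and the synaptotagmin Syt4 (5.94-fold). Among 77 actin and microtubule genes, 50 were higher and 23 lower (median 0.71, camera adjusted p = 0.0019). Tuba1a was 2.27-fold higher, while Arpc5l, a subunit of the Arp2/3 actin nucleator, was lower (log2 −3.27 ± 0.03).

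The injury and regeneration list stood among the highest, with 36 of 45 members higher and 5 lower, a median log2 of 1.14 and a camera adjusted p of 5.9e-06. Jun, Sox11 and Atf3, transcription factors of the axonal injury response, were 3.73-fold, 3.39-fold and 2.01-fold higher in IP (log2 1.90 ± 0.12, 1.76 ± 0.18 and 1.01 ± 0.08). Sprr1a, induced in regenerating neurons, was 2.49-fold higher (1.32 ± 0.06) and Gap43, a growth cone protein, 1.48-fold (0.57 ± 0.06). Gal, which encodes the neuropeptide galanin, went the other way with log2 −1.62 ± 0.03. Immediate early genes had 6 of 10 members higher (median 1.15, camera adjusted p = 0.019, adjusted p = 0.098 with an estimated correlation, and camera adjusted p = 0.05 by library total), with Dusp1 at 5.58-fold. Subtype markers were divided. Nociceptor genes had 7 members higher and 7 lower of 18 (median −0.02, mean 0.05, camera direction up, adjusted p = 0.65), with Ret 5.63-fold and Adcyap1 3.06-fold higher but Gfra2 at log2 −4.47 ± 0.33 and Tac1 at −2.27 ± 0.19. Mechanoreceptor and proprioceptor genes had 3 higher and 7 lower of 12 (median −0.60, camera adjusted p = 0.50), with Nefh 1.84-fold higher and Etv1 at log2 −3.19 ± 0.41. Ion channel genes had 12 higher and 6 lower of 24 (median 0.73, camera adjusted p = 0.23), with Cacnb3 5.39-fold higher.

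Stress-response, translation factor and proteasome genes also stood high in IP. All 21 tested members of the integrated stress response list were called, 18 higher and 3 lower (median 1.61, camera adjusted p = 0.0019), among them the asparagine synthetase gene Asns at 7.06-fold, the serine synthesis gene Phgdh at 5.10-fold and the transcription factor gene Atf4 at 2.87-fold. In the unfolded protein response list 14 of 18 were higher and 1 lower (median 0.82, camera adjusted p = 0.0074), with the chaperone genes Hspa5 at 2.89-fold and Calr at 2.57-fold. Translation factors had 32 of 56 members higher and 9 lower (median 0.53, camera adjusted p = 0.0019), with Eef1a2 at 7.10-fold, Eef2 at 4.04-fold and Eef1a1 at 2.97-fold. Proteasome genes had 23 of 36 higher and 5 lower (median 0.34, camera adjusted p = 0.0044), with Psmd4 at 3.51-fold. The heat shock gene Hspa8 was 6.71-fold higher (log2 2.75 ± 0.02) and Hsp90ab1 2.91-fold. Ywhag (7.12-fold), Nars (5.24-fold), Aldoa (3.22-fold), S100a10 (2.63-fold) and S100a13 (2.53-fold) were among the 12 with the smallest p.

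Nuclear and mitochondrial genes for respiration were far apart. Of 87 nuclear-encoded oxidative phosphorylation genes 55 were higher and 19 lower (median 0.24, camera adjusted p = 0.0021), including Atp5b at 3.08-fold. All 13 mitochondrially encoded mRNAs were lower, with a median of −4.24 (camera adjusted p = 2.2e-07). These RNAs are translated by mitochondrial ribosomes, which carry no RPL22. mt-Nd4 stood at log2 −5.19 ± 0.03 and mt-Atp6 at −5.04 ± 0.03, and the mitochondrial ribosomal RNA mt-Rnr2 at −4.79 ± 0.02. Cytosolic ribosomal protein mRNAs had 68 of 81 members lower and 10 higher with a median of −0.41 (camera adjusted p = 1.8e-05), but by library total their median was 0.50, and their median ranked at percentile 58.1 of expression-matched lists. Rplp1 stood at log2 −1.27 ± 0.02. Rpl22 itself was at −0.80 ± 0.04 but above 0 by library total (0.11). Mitochondrial ribosomal protein mRNAs had 17 higher and 30 lower of 76 (median −0.12, camera adjusted p = 0.34, median 0.78 by library total). Bc1, a neuronal noncoding RNA that is not translated, was at log2 −8.01 ± 0.04, with 12763 and 10236 counts in the input pools and 133 and 111 in IP.

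Of the marker lists of other cell types, 1 passed camera in IP against input. Schwann cell genes had 13 of 18 members lower and 1 higher (median −1.46, camera adjusted p = 0.0027). The myelin gene Mbp stood at log2 −4.10 ± 0.10 and S100b at −0.95 ± 0.05 (−0.05 by library total, adjusted p = 0.28). The other lists did not pass camera, while fry, which does not compare a list with other genes, called satellite glia, macrophage, fibroblast, endothelial and proliferation genes lower (adjusted p up to 2.6e-05). Satellite glia genes had 7 lower and 2 higher of 15 (median −0.17, camera adjusted p = 0.17), although Apoe was at −3.11 ± 0.05 and Fabp7 at −2.71 ± 0.07. Macrophage and immune genes had 9 lower and 3 higher of 14 (median −0.88, camera adjusted p = 0.28, but 0.046, 0.04 and 0.029 without column 1 or 2 of input shGpr151 or column 3 of input with e5UTR), with H2-Aa at −5.67 ± 0.44 and C1qa at −2.92 ± 0.20 against Coro1a at 4.52-fold and Lgals3 at 2.47-fold. Fibroblast genes had 7 lower and 5 higher of 14 (median −0.44, camera adjusted p = 0.48), with Dcn at −4.19 ± 0.11, Fn1 at −2.71 ± 0.06 and Serpinf1 at 5.08-fold. Endothelial and mural genes had 3 lower of 5 (median −1.16, camera adjusted p = 0.33), and proliferation genes 7 lower and 2 higher of 13 (median −0.65, camera adjusted p = 0.33), with Cenpf at −2.63 ± 0.05 and Stmn1 1.86-fold higher. By library total the medians of satellite glia, macrophage, fibroblast and proliferation genes were above 0 (0.72, 0.02, 0.46 and 0.25). The 4 adult hemoglobin genes, markers of red blood cells, summed to 5034 and 4924 counts in the input pools and to 13 and 19 in IP, which was 0.0982% (95% interval 0.0523 to 0.168) and 0.135% (0.0811 to 0.211) of the input level.

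The remaining lists were mixed. Cholesterol synthesis genes had 8 higher and 8 lower of 22 (median 0.09, mean −0.18, camera direction down, adjusted p = 0.94), with Sqle 3.73-fold higher and Srebf2 at log2 −2.41 ± 0.03. Interferon-stimulated genes had 4 higher and 5 lower of 11 (median −0.08, mean 0.12, camera direction up, adjusted p = 0.99), with Ifi27 1.68-fold higher and Xaf1 at −2.72 ± 0.06. Fry called ion channel and nociceptor genes higher and mechanoreceptor, mitochondrial ribosomal protein, cholesterol synthesis and interferon-stimulated genes lower (adjusted p up to 0.00054). Adjusted over the list alone, the counts changed in the injury and regeneration list (37 higher, 5 lower), translation factors (32 and 8), oxidative phosphorylation (55 and 20) and mitochondrial ribosomal proteins (17 and 28), and were the same in the other lists. The lowest p-values among depleted genes belonged, beside mt-Rnr2 and Bc1, to Brd8, Zfp410, Unc13d, Ccdc62, St13, Nlrc3, Btbd7, Arcn1, Eapp and Dnajb14, with log2 ratios between −2.91 and −3.93. These genes had over 10000 counts in each input pool. How the authors' counting divided reads between overlapping or repeated sequences is not given in the sources used here, so the levels of these genes are uncertain.

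**Figure D2:**
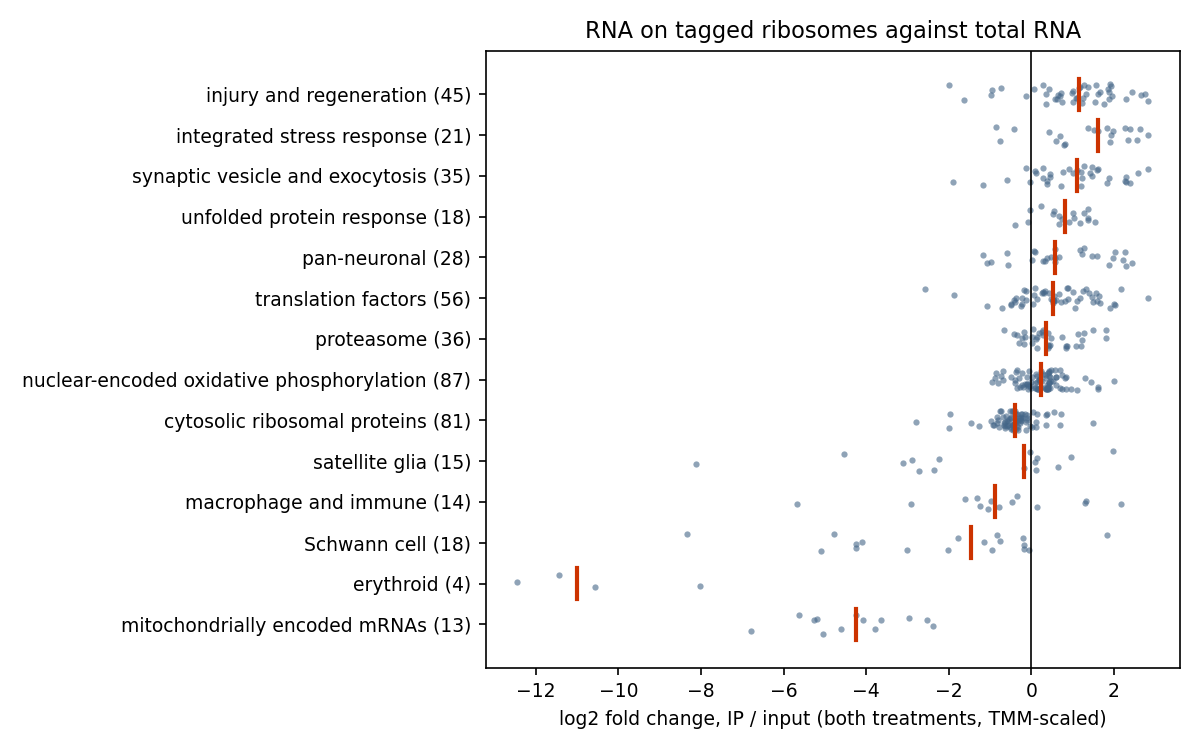
Log2 ratio of IP to input for the tested members of 14 gene lists (points, number of members in parentheses), with TMM scaling and the mean over both treatments; red bars are list medians. Mitochondrially encoded mRNAs lie at a median of −4.24 and regeneration genes at 1.14. Cytosolic ribosomal proteins lie at −0.41 here and at 0.50 when scaled by library total.

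The comparison of the input pools asked how total RNA differed when AAV-e5'UTR was added to AAV-shGpr151. Few genes differed, and most of these were lower with e5UTR. Of 8085 genes 1 was higher and 16 were lower with e5UTR by edgeR's quasi-likelihood test, 421 had an unadjusted p under 0.05, and the median size of the called changes was 1.36 on the log2 scale. Slc24a2, a sodium, calcium and potassium exchanger, had 284 counts with shGpr151 and 27 with e5UTR, a ratio of 0.0955 (95% interval 0.0618 to 0.142, adjusted p = 6.4e-21). Erap1, an aminopeptidase that trims antigenic peptides, had 169 and 27 counts (ratio 0.16, 0.103 to 0.242, adjusted p = 1.2e-07) and Trpm2, a calcium-permeable channel, 98 and 23 (0.236, 0.143 to 0.374, adjusted p = 3.8e-05). Add3, a cytoskeletal adducin, had 125 and 38 (0.305, 0.207 to 0.442, adjusted p = 1.6e-05), and the cell adhesion gene Chl1 of the injury and regeneration list 96 and 37 (0.387, 0.257 to 0.571, adjusted p = 0.0011). Abundant transcripts with smaller falls were Lrrc17 (log2 −0.43 ± 0.03, 14965 and 11080 counts in input and 0 in both IP pools), Bc1 (−0.31 ± 0.03), Elp6 (−0.29 ± 0.03), Dbi (−0.18 ± 0.03) and Timm22 (−0.18 ± 0.04). Reads can move between gene IDs in these input pools. For Ptp4a1, chosen after its values were seen, 1 ID fell from 57 counts to 0 while the other rose from 17 to 69. Such a move was not checked for the genes called in input, Lrrc17 included.

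The only gene called higher was Acbd6, with 2 and 23 counts (ratio 11.6, 2.85 to 101), and its adjusted p of 0.0094 became 0.34 with DESeq2 and 0.082 with limma-voom. Ccdc36 had 73 and 7 counts (adjusted p = 0.0022) and Nono 123 and 63 (adjusted p = 0.0094, and 0.051 with limma-voom). Without column 1 of input shGpr151 the calls were 11 and those of Trpm2 and Chl1 ended (log2 −1.57 and −1.22, adjusted p = 0.057 for each). The call of Ccdc36 ended without any 1 of the shGpr151 columns (adjusted p up to 0.071), that of Acbd6 without shGpr151 column 2 or 3 or e5UTR column 3 (up to 0.17) and that of Nono without shGpr151 column 2 or 3 or e5UTR column 1 or 2 (up to 0.2). No regeneration regulator passed the test. Log2 changes were 0.27 ± 0.15 for Atf3, 0.01 ± 0.26 for Jun, −0.34 ± 0.39 for Sox11, −0.05 ± 0.11 for Sprr1a and −0.11 ± 0.10 for Gap43, with adjusted p from 0.966 to 0.998. Avil (0.49 ± 0.27) and Rpl22 (0.05 ± 0.06) did not pass either. Of the 26 lists 0 passed camera, camera with an estimated correlation or fry, and 2 had an unadjusted camera p under 0.05, immediate early genes (0.0173, median 0.27) and Schwann cell genes (0.0197, median 0.17), each with an adjusted p of 0.26. Fry's mixed test, which asks whether members changed in either direction, passed 7 lists, among them oxidative phosphorylation (adjusted p = 1.8e-06). Median and camera direction were opposite for translation factors, the proteasome, cholesterol synthesis, interferon-stimulated genes and oxidative phosphorylation, whose median rounded to 0. Median and mean were opposite for mechanoreceptor, ion channel and interferon-stimulated genes. Chl1 was the sole called member of any list over all genes. Adjusted over the list alone, mt-Nd4 (log2 0.10 ± 0.03) and Phgdh (1.17 ± 0.35) were also higher.

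The comparison of the IP pools asked how RNA on the tagged ribosomes differed with e5UTR. Ubb, the redox enzyme gene Prdx1 and 43 of 87 oxidative phosphorylation genes were higher, and 6 of 13 mitochondrially encoded mRNAs were lower. Of 659 genes low in IP relative to input (log2 below −2, input above 100 CPM, thresholds chosen after seeing the data), 327 were lower and 8 higher. Most called changes were of less than 1.5-fold. Of 8085 genes 407 were higher and 567 lower (12% called), 261 of them by at least 1.5-fold and 79 by at least 2-fold, with a median size of 0.38 on the log2 scale. Of the lower genes 260 had no symbol or a predicted name, against 15 of the higher. RLE size factors moved the median of all genes by −0.07 and gave 197 higher and 754 lower, and library totals gave 359 and 617. Leaving out any 1 of the 6 IP columns gave 103 to 121 higher and 658 to 697 lower, and moved the median of all genes by −0.10 to −0.09. Small changes thus depend on the scaling. The shift was alike whichever IP column was left out, so a call that ended without a column does not by itself set that column apart.

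Ubb, a polyubiquitin gene, had 5374 and 8980 counts in the IP pools, a ratio of 1.54 (95% interval 1.49 to 1.59, log2 0.62 ± 0.03, adjusted p = 5.8e-29), and 3002 and 2935 in input. Prdx1, a peroxiredoxin, was 1.49-fold higher (1.41 to 1.58, adjusted p = 5.4e-18), and Actg1, cytoplasmic gamma-actin, 1.82-fold (1.69 to 1.95, adjusted p = 9.3e-14). The other genes with the smallest p were Cryab (1.32-fold, a small heat shock protein), Rps27a (1.26-fold), Rps26 (1.23-fold), Dbi (1.19-fold), Rps9 (1.19-fold), S100a10 (1.17-fold), Ndufa4 (1.15-fold) and Lgals1 (1.12-fold). Taf9, a subunit of the general transcription factor TFIID, had 0 and 146 counts in IP, at least 44.9-fold higher, and 57 and 56 in input (adjusted p = 1.9e-17, not computed by DESeq2). Ak6, which shares a locus with Taf9 and was chosen after its values were seen, had 332 and 282 counts in IP (ratio 0.784, 0.666 to 0.921), and the sum of the pair differed 1.19-fold (1.03 to 1.38).

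Of 87 nuclear-encoded oxidative phosphorylation genes 43 were higher with e5UTR and 1 lower (median log2 0.13, camera adjusted p = 5.2e-09). Their median was 0.06 under RLE scaling and 0.03 to 0.04 without any 1 IP column, where the list still passed (adjusted p up to 0.0027). Cox4i1 rose by 0.22 ± 0.02 and Cox6b1 by 0.19 ± 0.02, while Atp5k was at −0.18 ± 0.02. Mitochondrial ribosomal protein genes had 16 higher and 2 lower of 76 (median 0.15, 0.07 under RLE, 0.04 to 0.07 without any 1 IP column, camera adjusted p = 0.00012 and up to 0.024 there), with Mrpl14 at 0.37 ± 0.07, Mrps33 at 0.24 ± 0.05 and Mrpl13 at −0.30 ± 0.06. The call of Mrpl14 ended without column 3 of IP with e5UTR (0.23, adjusted p = 0.066) and that of Mrps33 without 5 of the 6 IP columns (0.11 to 0.15). Proteasome genes had 9 higher and 1 lower of 36 (median 0.14, 0.07 under RLE, 0.02 to 0.07 without any 1 IP column, camera adjusted p = 0.0025, but up to 0.13 without column 1, 2 or 3 of IP shGpr151 or column 3 of IP with e5UTR), with Psmb3 at 0.24 ± 0.04 and Psmb6 at 0.21 ± 0.04. Their calls ended without column 1 of IP with e5UTR (0.12 and 0.06), that of Psmb3 also without column 2 of that group, and that of Psmb6 without column 1 or 2 of IP shGpr151. DESeq2 ended the calls of Mrps33, Psmb3 and Psmb6 (adjusted p = 0.081, 0.054 and 0.051). Cytosolic ribosomal protein genes had 35 higher and 6 lower of 81 (median 0.08, camera adjusted p = 0.00012, but a median of 0.01 and adjusted p = 0.14 under RLE, and a median of −0.02 to −0.01 without any 1 IP column). Their adjusted p was 0.13 with an estimated correlation. Rps29, among the most abundant mRNAs, was lower (−0.18 ± 0.02). Adjusted over the list alone, the counts were 50 higher and 1 lower for oxidative phosphorylation, 17 and 2 for mitochondrial ribosomal proteins, 11 and 1 for the proteasome and 42 and 7 for cytosolic ribosomal proteins. Beside these groups, genes low in IP relative to input (log2 below −2, input above 100 CPM, thresholds chosen after seeing the data) held 12.1% of the tested reads in IP shGpr151 and 9.8% in IP with e5UTR, against 51.6% in both input pools.

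Mitochondrially encoded mRNAs had 6 of 13 members lower in IP with e5UTR (median −0.27, camera adjusted p = 0.00012, adjusted p = 0.065 with an estimated correlation, 8 lower adjusted over the list alone). Without column 3 of IP with e5UTR the median was −0.43. These mRNAs were themselves low in IP relative to input (median −4.24), and the 659 genes low in IP as defined above had a median of −0.32 with e5UTR. Camera set the list against all other tested genes, not against genes low in IP alone. A fall particular to mitochondrially encoded mRNAs was therefore not tested. mt-Atp6 was at −0.55 ± 0.07, mt-Co2 at −0.37 ± 0.06 and mt-Nd5 at −0.92 ± 0.19, and the mitochondrial transfer RNA genes mt-Tq at −0.95 ± 0.05 and mt-Ts1 at −0.53 ± 0.05. The other genes with the smallest p among those lower were Ttf1 (−0.43 ± 0.03), Zfp410 (−0.37 ± 0.03), Brd8 (−0.34 ± 0.03), Eapp (−0.39 ± 0.03), Unc13d (−0.34 ± 0.03), Nanog (−0.38 ± 0.03), Nlrc3 (−0.30 ± 0.03), Snhg9 (−0.62 ± 0.06) and Gfod2 (−0.51 ± 0.05). Most of these were themselves depleted from IP, such as Zfp410 with 21791 and 21995 counts in input and 6221 and 5226 in IP. Here and below, the limit on read assignment given above for Zfp410 and Brd8 holds for the other depleted genes too, Nanog among them. The nuclear RNA Malat1, chosen after its values were seen, had 238 and 129 counts in IP (ratio 0.50, 0.40 to 0.622).

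The neuronal and regeneration lists did not pass camera in IP with e5UTR. Log2 changes in IP were 0.06 ± 0.08 for Atf3, 0.07 ± 0.10 for Jun, 0.14 ± 0.14 for Sox11, −0.10 ± 0.05 for Sprr1a and 0.15 ± 0.06 for Gap43, with adjusted p of 0.732, 0.74, 0.614, 0.222 and 0.0622, although Sprr1a passed as lower under RLE scaling (−0.17, adjusted p = 0.013) and without any 1 of the IP columns (−0.22 to −0.18). Gap43 passed with only the 6 libraries compared (adjusted p = 0.046). Avil (−0.05 ± 0.10) did not pass. The injury and regeneration list had 5 of 45 members higher (median 0.07, camera adjusted p = 0.063, and 0.037 with fry), including the neuropeptide genes Npy (0.20 ± 0.04) and Gal (0.22 ± 0.04) and Stmn2 (0.14 ± 0.02). The pan-neuronal list had 3 higher of 28 (median 0.01, mean −0.01, camera adjusted p = 0.64), with Uchl1 at 0.14 ± 0.02 and Sncg at 0.12 ± 0.02, and Rpl22 was at 0.20 ± 0.05. The calls of Stmn2, Sncg, Rpl22 and Spp1 ended under RLE scaling (log2 0.06, 0.05, 0.12 and 0.19) and with DESeq2 (adjusted p = 0.16, 0.21, 0.16 and 0.19). Without any 1 IP column the calls of Stmn2, Sncg, Uchl1, Rpl22 and Spp1 ended (lowest log2 0.03, 0.01, 0.04, 0.07 and 0.13), as did those of Npy without 5 of them (0.11) and of Gal and Calca without 4 (0.10 for each). That of Ntrk3 ended without column 2 of either group or column 3 with e5UTR (−0.89 to −1.09) and that of Scn8a without any shGpr151 column (1.18 to 1.46). Nociceptor genes had 1 of 18 higher (Calca, 0.22 ± 0.05, adjusted p = 0.11 with DESeq2), and mechanoreceptor and proprioceptor genes had 2 higher and 1 lower of 12 (medians 0.11 and 0.09, camera adjusted p = 0.58 and 0.64). Ntrk3, the receptor of neurotrophin-3, was at −1.13 ± 0.36 (53 and 26 counts, adjusted p = 0.06 with limma-voom). Scn8a, a sodium channel of both the mechanoreceptor and ion channel lists, was at 1.41 ± 0.43 (15 and 44) and Spp1 at 0.26 ± 0.07. Synaptic vesicle genes had 1 higher and 1 lower of 35 (median −0.01, mean −0.04, camera direction up, adjusted p = 0.95), namely Atp6v0c (0.30 ± 0.05) and Pcsk1n (−0.29 ± 0.07), and ion channels 1 higher of 24 (median −0.15, camera adjusted p = 0.68). Fry called the ion channel list lower (adjusted p = 0.025).

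Of the remaining lists, interferon-stimulated genes passed camera in IP with e5UTR. They had 3 of 11 higher (median 0.26, camera adjusted p = 0.0091, adjusted p = 0.085 with an estimated correlation, and up to 0.11 without column 1 or 2 of IP shGpr151 or column 1 or 3 of IP with e5UTR, and a median of 0.13 to 0.17 without any 1 IP column but the last of these), namely B2m (0.30 ± 0.05), Ifitm3 (0.27 ± 0.07) and Ifi27 (0.25 ± 0.06), of which the last was not called under RLE (adjusted p = 0.058). DESeq2 ended the calls of Ifitm3 and Ifi27 (adjusted p = 0.072 and 0.21). In the integrated stress response list Atf4 (−0.30 ± 0.08) and Chac1 (−0.70 ± 0.21) were lower and Eif4ebp1 (0.49 ± 0.16, adjusted p = 0.091 under RLE, 0.21 with DESeq2 and 0.057 without a filter) higher among 21 (median 0.07, mean −0.01, camera adjusted p = 0.64), and the 18 unfolded protein response genes had a median of 0.08 (camera adjusted p = 0.58). Translation factors had 4 higher and 2 lower of 56 (median 0.08, camera adjusted p = 0.10), with Eif1b at 0.31 ± 0.05, Eif1 at 0.17 ± 0.03 and Eef1a2 at −0.40 ± 0.06. Cytoskeleton genes had 11 higher and 4 lower of 77 (median 0.04, camera adjusted p = 0.24), with Dynll1 at 0.24 ± 0.04 beside Actg1. Cholesterol synthesis genes had 2 lower of 22, Msmo1 (−0.38 ± 0.08) and Srebf2 (−0.22 ± 0.05), with a median of 0.06 (camera adjusted p = 0.64). Without any 1 IP column the calls of Ifitm3, Ifi27 and Eif1 ended (lowest log2 0.16, 0.10 and 0.07), as did that of Eif4ebp1 without 5 of them (0.28). Dynll1 ended without shGpr151 column 2 or e5UTR column 1 (0.11 and 0.14) and Chac1 without shGpr151 column 3 (−0.68, adjusted p = 0.057).

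No list of markers of other cells passed the test in IP with e5UTR. Satellite glia genes had Fabp7 higher (0.55 ± 0.12) and Apoe lower (−0.32 ± 0.09) among 15 (median 0.04, mean −0.03, camera direction down, adjusted p = 0.87). Schwann cell genes had 1 higher of 18 and a median of 0.00 (−0.03 with genes at 0 counts placed at their bound, camera direction up, adjusted p = 0.68). Fibroblast genes had 1 higher of 14 (median 0.15, camera adjusted p = 0.086), a call that ended when adjusted over the list alone. Of 14 macrophage and immune genes Csf1r was lower (−1.20 ± 0.39, 62 and 29 counts, adjusted p = 0.15 with only the 6 libraries compared), with a list median of −0.02, a mean of −0.07 and camera's direction up (adjusted p = 0.64). The 5 endothelial and mural genes had a median of 0.60 (camera adjusted p = 0.063, and 0.044 without column 2 of IP with e5UTR) and the 10 immediate early genes a median of 0.06 and a mean of −0.01 (camera adjusted p = 0.87). Proliferation genes had 3 higher and 3 lower of 13 (median 0.03, camera adjusted p = 0.68), among them Stmn1 (0.17 ± 0.04, adjusted p = 0.15 under RLE and 0.26 with DESeq2) and Ccnb1 (−0.90 ± 0.23). Adjusted over the list alone, the counts were 8 lower for mitochondrially encoded mRNAs as above, 4 higher for interferon-stimulated genes, 5 higher and 1 lower for pan-neuronal genes, and otherwise, fibroblast genes aside, the same in the lists named here. Without column 3 of IP shGpr151 the call of Ccnb1 ended (−0.70, adjusted p = 0.06), as did those of Csf1r (−1.24 to −0.82) without 4 of the IP columns and of Stmn1 without any 1 (0.06 to 0.09).

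**Figure D3:**
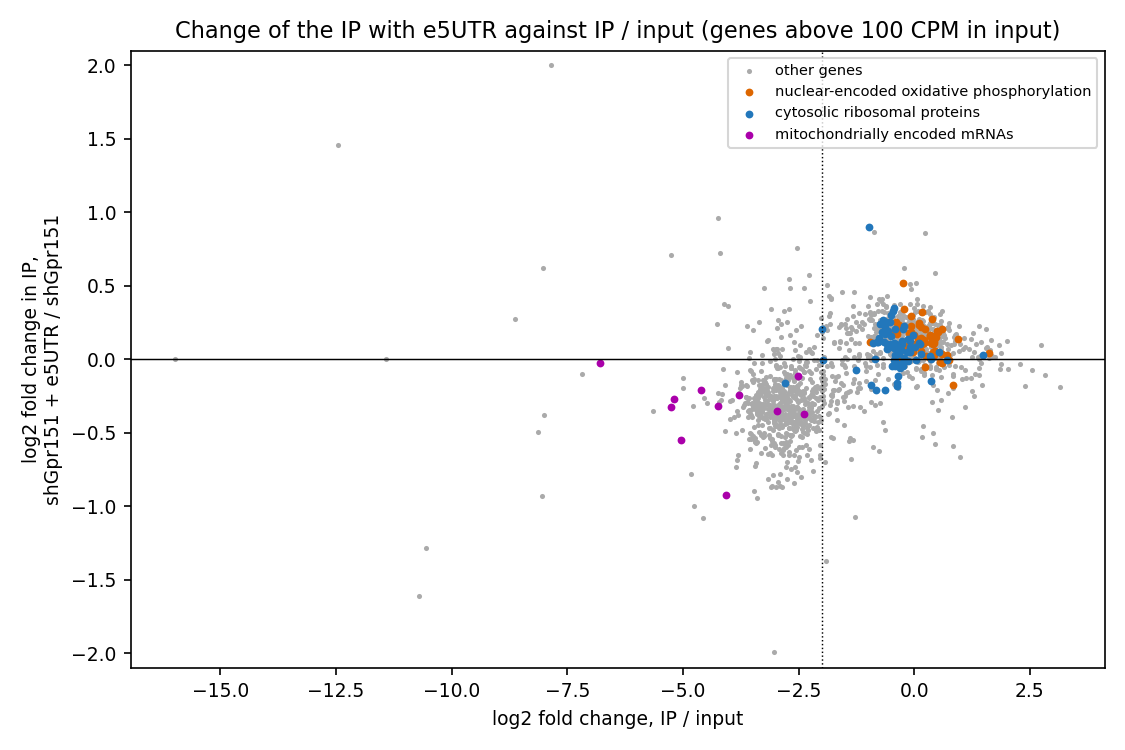
Log2 ratio of IP with e5UTR to IP shGpr151 against the log2 ratio of IP to input, for the 1418 genes above 100 CPM in input (points), with TMM scaling. Orange marks nuclear-encoded oxidative phosphorylation, blue cytosolic ribosomal proteins and purple mitochondrially encoded mRNAs, and genes with 0 counts in a pool sit at fitted values that are no bound. The dotted line marks −2 on the horizontal axis, and 1 gene beyond the vertical limit of 2 is drawn at it. To the left of the line 659 genes had a median of −0.32, and the other 759 a median of 0.11. The median of all genes moves by −0.07 under RLE scaling.

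The interaction of fraction and treatment asked whether RNA on tagged ribosomes changed beyond the change of total RNA. With e5UTR the IP rose relative to input for Ubb, Prdx1, Dbi and Actg1 and fell for mt-Tq, mt-Atp6 and a set of IP-depleted genes. Of 8085 genes 146 had a higher and 319 a lower effect in IP than in input (465 called, 5.8%). RLE scaling gave 72 higher and 409 lower, and leaving out any 1 of the 6 IP columns 46 to 50 higher and 399 to 417 lower. The difference between the effects was 0.65 ± 0.05 on the log2 scale for Ubb (adjusted p = 3.9e-18), 0.59 ± 0.06 for Prdx1 (2.7e-13), 0.44 ± 0.03 for Dbi (3.1e-16), which fell in input and rose in IP, and 0.76 ± 0.12 for Actg1 (2.3e-05). Slc24a2 (3.28 ± 0.31) and Chl1 (1.55 ± 0.30) were lower with e5UTR in input and had ratios of 0.932 (95% interval 0.698 to 1.25) and 1.14 (0.915 to 1.41) in IP. Rps27a (0.35 ± 0.04), Rps26 (0.33 ± 0.03), Cryab (0.41 ± 0.05), S100a10 (0.24 ± 0.03), Ndufa4 (0.24 ± 0.04) and Lgals1 (0.17 ± 0.03) were among the other genes of smallest p in that direction, beside Taf9, and the call of Lgals1 ended without any 1 IP column (adjusted p up to 0.14).

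The lowest interaction values of smallest p belonged to mt-Tq (−0.87 ± 0.05), Gfod2 (−0.50 ± 0.06), Ttf1 (−0.43 ± 0.04), Polg2 (−0.42 ± 0.05), Nanog (−0.40 ± 0.04), Eapp (−0.40 ± 0.04), Zfp410 (−0.39 ± 0.03), Fam193a (−0.38 ± 0.05), Dnajb14 (−0.36 ± 0.04), Brd8 (−0.33 ± 0.03), Unc13d (−0.32 ± 0.03) and Nlrc3 (−0.31 ± 0.03). Mitochondrially encoded mRNAs had 5 lower of 13 (median −0.26, camera adjusted p = 0.013, adjusted p = 0.28 with an estimated correlation), with mt-Atp6 at −0.52 ± 0.08 and mt-Co2 at −0.34 ± 0.07. Here too they were not set against other genes low in IP. Oxidative phosphorylation genes had 15 higher and 1 lower of 87 (median 0.12, camera adjusted p = 0.00085 and 0.051 under RLE, where the median was 0.05). Cytosolic ribosomal proteins had 25 higher and 4 lower of 81 (median 0.09, camera adjusted p = 0.011, but 0.02 and adjusted p = 0.28 under RLE, and adjusted p = 0.31 with an estimated correlation). Mitochondrial ribosomal proteins had 4 higher and 1 lower of 76 (median 0.14, camera adjusted p = 0.025, but 0.08 and adjusted p = 0.15 under RLE, and adjusted p = 0.15 with an estimated correlation). The call of mitochondrially encoded mRNAs ended without column 2 of input with e5UTR, column 3 of IP shGpr151 or column 1 of IP with e5UTR (camera adjusted p up to 0.12), and their median was −0.40 without column 3 of IP with e5UTR. That of oxidative phosphorylation ended without any 1 IP column (up to 0.2, median 0.02 to 0.04). That of cytosolic ribosomal proteins ended without any 1 IP column, input shGpr151 column 2 or input e5UTR column 2 or 3 (up to 0.71, median −0.01 to 0.08), and that of mitochondrial ribosomal proteins without any column but input shGpr151 column 1 (up to 0.35, median 0.04 to 0.16). Adjusted over the list alone, these 4 lists had 7 lower, 22 higher and 2 lower, 32 higher and 7 lower, and 5 higher and 1 lower.

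Regeneration regulators did not pass the interaction test. The values were −0.21 ± 0.16 for Atf3, 0.07 ± 0.28 for Jun, 0.48 ± 0.41 for Sox11, −0.05 ± 0.12 for Sprr1a and 0.26 ± 0.11 for Gap43, with adjusted p from 0.215 to 0.949. Gpr151 (0.39 ± 0.41), Avil (−0.53 ± 0.28) and Rpl22 (0.14 ± 0.08) did not pass either. The injury and regeneration list (3 higher of 45, median 0.09), pan-neuronal list (2 higher of 28, median −0.02), proteasome (2 higher of 36, median 0.14, 8 higher and 1 lower adjusted over the list alone), translation factors (2 higher of 56, median 0.05), interferon-stimulated genes (1 higher of 11, median 0.26), satellite glia (1 higher and 1 lower of 15, median −0.37) and Schwann cell genes (1 higher of 18, median −0.15) had camera adjusted p of 0.35, 0.99, 0.059, 0.39, 0.18, 0.72 and 0.55. The other 15 tested lists did not pass camera either, and their lowest adjusted p was 0.23. Among the members of those named here 2 proliferation genes were lower, including Ccnb1 (−1.22 ± 0.29). In the cytoskeleton list 2 were higher and 2 lower, and in the synaptic vesicle list 1 was higher. The proteasome passed with fry (adjusted p = 0.012) and without column 3 of input shGpr151 (camera adjusted p = 0.032), and endothelial and mural genes without column 1 of either input group (0.026 and 0.031). Median and mean differed in sign for cytoskeleton, mechanoreceptor and fibroblast genes, and median and camera direction for mechanoreceptor, fibroblast, macrophage, integrated stress response and synaptic vesicle genes.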

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

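Among the tests in this part, those of a divided read pool, of separately sequenced libraries, of carry-over, of a shared RNA source and of a loss of reads were chosen only after the result was seen. The other splits of the samples were chosen before. An effect of AAV-e5'UTR was not tested, because each group holds only 1 pool.

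For 465 genes the effect of e5UTR in IP differed from that in input by the interaction test. The 45 given here, 27 of them higher in IP and 18 lower, are genes of smallest p in that test and some called members of the lists. Other genes named in the report passed it as well. All values here are that difference on the log2 scale. The ubiquitin gene Ubb stood at 0.65 and Rps27a, which encodes ubiquitin fused to a ribosomal protein, at 0.35. The redox enzyme gene Prdx1 was at 0.59, gamma-actin Actg1 at 0.76, the acyl-CoA binding protein gene Dbi at 0.44, Cryab at 0.41, S100a10 at 0.24 and Lgals1 at 0.17. Other ribosomal protein and translation factor genes were Rps26 at 0.33, Rps7 at 0.24, Eif1 at 0.20, Eef2 at 0.46 and Mrpl41 at 0.48, with Mrpl13 at −0.38. Respiratory genes were Ndufa4 at 0.24, Cox4i1 at 0.22, Cox6b1 at 0.19 and Atp5k at −0.23, and the mitochondrially encoded mt-Co2, mt-Atp6 and mt-Tq at −0.34, −0.52 and −0.87. Neuronal and injury genes were Gal at 0.24, Npy at 0.32, Uchl1 at 0.18, Sncg at 0.14, Chl1 at 1.55 and Slc24a2 at 3.28. Glial and immune genes were Fabp7 at 0.51, Apoe at −0.42 and B2m at 0.31. Psmb3 was at 0.33, Atp6v0c at 0.34, and the cell cycle gene Ccnb1 at −1.22. Genes depleted from IP were Zfp410 at −0.39, Eapp at −0.40, Ttf1 at −0.43, Brd8 at −0.33, Nanog at −0.40, Nlrc3 at −0.31, Unc13d at −0.32, Polg2 at −0.42, Gfod2 at −0.50, Fam193a at −0.38 and Dnajb14 at −0.36. Taf9, with no count in IP shGpr151, had a fitted value of 8.02, which is no bound. With 1 of the 12 columns left out, the calls of Eef2 (without any 1), Npy and Sncg (without 9 of them), Mrpl41 (8), B2m, Cox6b1, Eif1, Lgals1, Psmb3 and Uchl1 (6), Fabp7 and Gal (5), Cox4i1 (4) and Atp6v0c (3) ended. RLE scaling ended those of Npy, Uchl1, Sncg, Eef2, Eif1, Mrpl41 and Psmb3, and DESeq2 those of Gal, Npy, Sncg, Fabp7, Eef2, Eif1, Mrpl41 and Psmb3. The call of Eef2 also ended by library total, with limma-voom and without a filter, and that of Psmb3 with limma-voom. Groups of 3 columns were not tested for a column far from the others.

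The real grouping was set against other splits of the columns. With each group counted as 1 pool there are 4 samples, whose splits are too few for a share under 0.05, and the counts here compare columns of the same pools. For IP against input 1 of the 100 splits drawn gave as many genes as the 6196 called, the real one itself, and the highest other split gave 4. As many as its 13 gene lists came from 3 of 100 splits, with a highest other count of 13. For the interaction 1 of 100 splits reached 465 genes and the highest other gave 462. That split moved 10 columns but kept the IP groups whole. The 10 splits that did so, the real one included, gave at least 402 genes, while the 90 that mixed the IP groups gave at most 3, so the count followed the columns of the IP pools. For its 4 lists 10 of 100 splits gave as many, with a highest other count of 8. For the e5UTR effects 6 columns have 10 splits. As large a count came from 1 of 10 splits for the 17 genes in input (highest other 3), from 10 of 10 for the 0 lists in input (1), from 1 of 10 for the 974 genes in IP (2), and from 1 of 10 for the 6 lists in IP (3).

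The 3 columns of each group differed by little more than counting noise. Separately sequenced libraries, each deposited at its own depth, were argued against by the column totals, whose variance was at most 1.25 times the mean in any group. A single read pool divided into 3 columns is a candidate explanation, since the median gene's chi-square was at most 1.12 times the counting value. What stays open is the small excess of 1.24 to 1.39 times over all genes, and whether repeat sequencing of 1 RNA sample brought to equal depth gave the columns. No biological explanation was tested for this pattern.

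Genes low in IP fell further in the IP with e5UTR: 659 genes had a median of −0.32 there (quartiles −0.42 and −0.19), 90.6% of them were below 0, and their median in input was 0.0. Of the 659, 327 were called lower and 8 higher, against 60 and 268 of the other 759 genes above 100 CPM in input. No symbol or only a predicted name was found for 336 of the 659 and 75 of the 759. Carry-over of all lysate RNA alike, as the source of the reads of the 659, was argued against. Hemoglobin mRNA stood in IP at no more than 0.211% of its input level, whereas the median of the 659 was 13.4%. Hemoglobin cannot speak for carry-over of other RNAs. In IP against input Apoe stood at log2 −3.11, Fabp7 at −2.71 and mitochondrially encoded mRNAs at a median of −4.24, so uneven carry-over stays open. A source shared by many genes stays open, since the SD of the effect between genes beyond counting error was 0.09 among the more abundant of the 659 and 0.11 among other genes as abundant. An effect of AAV-e5'UTR on these RNAs cannot be told apart from a difference between the 2 pull-downs, because each group holds 1 pool.

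Oxidative phosphorylation and cytosolic ribosomal protein mRNAs had medians of 0.13 and 0.08 for the e5UTR effect in IP. The first was 0.06 under RLE scaling and 0.03 to 0.04 without any 1 IP column. The second was 0.01 under RLE and −0.02 to −0.01 without any 1 IP column (adjusted p up to 0.61), so a rise of ribosomal protein mRNAs is not established. A loss of reads from genes low in IP would raise all other genes alike. Against such genes alone the ribosomal protein median of 0.08 ranked at percentile 8.75 of matched random lists, whose own median was 0.11. The ribosomal protein mRNAs thus rose no more than other genes of like expression. The median of all 5862 tested genes with a log2 ratio of IP to input above −1 was 0.05, below the 0.11 of the matched lists. A loss that raised all of them alike would not give this gap, so these values argue against it as the whole cause. It stays possible as a part of the rise, and a rank that is not extreme does not show it to be a cause. The oxidative phosphorylation median of 0.13 ranked at percentile 97.69, between the limits of 95 and 99 set for the test, and stays open. An effect of AAV-e5'UTR on these mRNAs cannot be told apart from a difference between pull-downs, with 1 pool in each group.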

How the results depend on the processing

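The test of changes beyond 1.5-fold, the fit of the 4 pools as samples and the fit without genes low in IP were chosen only after the result was seen; all other alternatives were fixed before. The gene counts of all 4 comparisons stayed within 1.5 times of those reported under RLE scaling (17, 951, 6307 and 481 in the order input, IP, IP against input and interaction), library totals (17, 976, 7193 and 477), limma-voom (14, 968, 6042 and 381), no filter (20, 942, 8614 and 446), a mean count of at least 10 (15, 1010, 5348 and 464) and an adjusted p of 0.10 (20, 1279, 6486 and 602), and with only the 6 libraries compared (16 and 1084). DESeq2 called 606 genes in IP (99 higher, 507 lower) and 12, 7470 and 379 in the others; the cause was not tested. Of the 974 genes called in IP, 764 were also called under RLE scaling. Directions moved more than these totals. In IP the calls were 407 higher and 567 lower, but 197 and 754 under RLE. For the interaction they were 146 higher and 319 lower, but 72 and 409 under RLE. For IP against input they were 3133 higher and 3063 lower, but 5216 and 1977 by library total.

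By the construction of a stricter test, a change beyond 1.5-fold was called for 5 genes in input, 4 in IP, 4509 for IP against input and 5 for the interaction. Of the 5862 genes with a log2 ratio of IP to input above −1, 5390 passed the filter when filtered and scaled among themselves, and 429 of these were called in IP, 214 higher and 215 lower. The 4 pools as samples gave 5651 genes for IP against input. Leaving out 1 column gave 11 to 18 genes in input, 766 to 817 in IP, 6047 to 6548 for IP against input and 396 to 463 for the interaction, with 11 without column 1 of input shGpr151, and 17 to 26 gene lists. Camera's 23 list calls became 40 with fry, which does not compare a list with other genes, 19 under RLE, 23 by library total and 16 with an estimated correlation.

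By library total, which moved all IP to input ratios by 0.90, the ratio reversed for Rpl22 (0.11), Rps19 (0.12), B2m (0.39), cytosolic ribosomal proteins (0.50) and mitochondrial ribosomal proteins (0.78). With fry the interferon-stimulated list turned from up to down, at an unchanged median of −0.08, and the cause was not tested. Of 229 results for named genes, 213 were the same under RLE (14 lost, 2 gained), 223 by library total (2 lost, 1 gained), 224 with limma-voom (5 lost) and 226 without a filter (2 lost, 1 gained). DESeq2 left 196 the same, lost 21, gained 1 and gave no adjusted p for 11. Of 96 list results, RLE left 92 the same and lost 4.

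The replicate numbers did not pair the columns. Over the 18 pairs of same-numbered columns the correlations of their deviations from the group means ran from −0.034 to 0.061 over 1449 genes, and 8 correlated best with their own number. With the number as a block the calls were 15 in input and 924 in IP. With treatment and number together as the block they were 6105 for IP against input and 404 for the interaction, and 20 lists passed in all. The blocks ended the call of Ccdc36 in input (adjusted p = 0.14) and 3 interaction lists, cytosolic and mitochondrial ribosomal proteins and mitochondrially encoded mRNAs (adjusted p = 0.063 for each), and changed no other call of a named gene or list.

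Many changes of 1.5-fold would be missed at this depth even with the columns as replicates. In simulated counts 28% of genes changed 1.5-fold were recovered in input, 36% in IP and 6% for the interaction. The alternatives for a pseudocount were not run, since the values are counts.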

Other observations

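The lists set against genes not low in IP, the sums over gene IDs that share a locus or a symbol, and the genes named in this part were chosen only after the result was seen.

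Among the 5862 tested genes with a log2 ratio of IP to input above −1, whose median change with e5UTR in IP was 0.05, mitochondrial ribosomal protein genes had a median of 0.15 (percentile 99.63 of matched random lists) and interferon-stimulated genes 0.27 (99.17). Proteasome genes had a median of 0.14 (93.51), and the injury and regeneration list one of 0.07 (42.45). These percentiles describe the 2 IP pools and hold no replicate check. They were computed with all columns only. Over all tested members the mitochondrial ribosomal protein median was 0.04 to 0.07 without any 1 IP column. The interferon-stimulated median was 0.13 to 0.17 without any 1 IP column but column 3 with e5UTR.

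Ptp4a1, a phosphatase gene, is listed under 2 IDs. One had 17, 69, 339 and 0 counts in input shGpr151, input with e5UTR, IP shGpr151 and IP with e5UTR, the other 57, 0, 73 and 423. Their sums of 74, 69, 412 and 423 had ratios of e5UTR to shGpr151 of 0.937 in input (95% interval 0.665 to 1.32) and 0.947 in IP (0.825 to 1.09). Taf9 and its neighbour Ak6 summed to 159 and 164 counts in input (1.04, 0.828 to 1.3). Cnot9 had 16 and 0 counts in input and 35 and 46 in IP. An RNA without a symbol, ENSMUSG00000123637, had 156 and 2 counts in IP, a ratio of 0.0118 (0.00142 to 0.0434).

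Erap1 and Add3, both lower with e5UTR in input, had 18 and 38 counts (ratio 1.95, 1.08 to 3.63) and 26 and 43 counts (1.53, 0.917 to 2.59) in IP, and their interaction values were 3.57 ± 0.55 and 2.31 ± 0.45 on the log2 scale. Nanog, a transcription factor of pluripotent cells, had 11542 and 11670 counts in input and 5047 and 4201 in IP. Whether these reads came from Nanog mRNA was not checked. How the counting divided reads between overlapping or repeated sequences is not given, so its level is uncertain. Gene IDs without a symbol held 17.5% to 17.8% of the counts of an input column, 7.3% of an IP shGpr151 column and 5.9% to 6.0% of an IP column with e5UTR.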
